A study of Panonychus citri with 16 samples.

How the data were processed

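PolyA RNA of whole adult females of the citrus red mite Panonychus citri was sequenced in 16 libraries, 4 biological replicates of each of 4 populations. Per the labels' protocols, each library came from a pool of 100 to 130 mites reared on lemon leaves, and a stranded TruSeq kit and paired reads of 125 bases were used. The deposited table lists 17682 assembled contigs, each with an estimated count and a TPM value in every library. TPM, a length-corrected relative abundance, divides by transcript length and has the same sum in every library. The estimated counts deposited by the authors need not be whole, because a read that matches several contigs is shared between them. Per the submitters' processing notes, FastQC 0.11.4, kallisto, sleuth 0.29.0, R 3.4.4, edgeR 3.20.9 and limma 3.43.9 were used, and the notes assign no role to any of them. The origin of the contig set, and the settings with which the deposited TPM and estimated counts were made, are not given in the sources used here.

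The identifiers consist of the name of a population and a number, and the files do not pair them with gene names. Of the 17682 identifiers, 0 matched the table of gene names used here. The 27 gene lists fixed before the data were examined (detoxification enzymes, transporters, mitochondrial targets, housekeeping and other-organism genes) therefore had 0 lists with a matched member, and no list was tested. No genome sequence was used, so no positions are given.

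Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood test in robust mode. All 16 libraries entered one model with 1 mean per population, so that the populations shared one estimate of the spread. Library sizes were scaled with TMM factors. Transcripts with low counts were removed with filterByExpr, which left 12174 transcripts that held at least 99.9% of the counts of each library. A transcript was called changed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The 6 comparisons between populations were tested as contrasts of this model. Levels are given as the deposited TPM, mean ± SD over 4 libraries, and fold changes with an approximate standard error (SE). This SE is the absolute log2 fold change divided by the square root of the F statistic of the edgeR test. The labels call the replicates biological, and each is a separate RNA extraction from a pool of mites. The p-values therefore rest on the spread between pools within populations, estimated over all populations together. This shared spread is not that of any 1 population. The median dispersion was 0.24 among the Rasht libraries and 0.019 among the others. A population stands for each resistance level (a pair of them for the high level), so the level and the population cannot be separated.

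Named transcripts were chosen by a rule written before the data were examined. In each comparison these were the 2 with the largest rise and the 2 with the largest fall among calls with no overlap between the libraries compared and a mean log2 CPM of at least 2. Overlap was judged on TMM-scaled log2 CPM here and in all counts of transcripts whose libraries did not overlap. Transcripts with fractional counts were taken to share reads with another contig, and their values are uncertain to that extent. All named transcripts except Lahi_contig_3092 had fractional counts; counts within 0.001 of a whole number were taken as whole. Where a population had no counts at all, the fold is a lower bound against 3 counts over the group, and where it had 1 to 3 counts the ratio is given with an exact 95% interval for counting error only.

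The test was checked on simulated counts for Sari against Rasht. Among 11994 transcripts tested, 73% of 100 changes of 1.5 and 91% of 100 changes of 3 on the log2 scale were called, and 4 unchanged transcripts were called. This check gave all populations the same spread, without the larger spread of the Rasht libraries, so it holds for that setting only. Unchanged groups that kept the Rasht spread gave a mean of 70.6 calls for this comparison. Unchanged groups were also simulated 20 times with the spread of the Rasht libraries and that of the others kept apart, to show what comparisons against the same Rasht libraries give without any effect; the simulated, independent and split values for transcripts called in both highly resistant populations against both others were added after seeing the data. The 6 counts of calls were recomputed with DESeq2 size factors, upper-quartile factors, no filter, a filter of CPM 1 in 4 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), only the 2 populations compared, the replicate number as a block, the adjusted p alone, and each library of the populations compared left out in turn. Counts shared between comparisons were recomputed in the same ways except with only the 2 populations compared, and correlations of fold changes with the other scalings, the other filters and the block. Rasht replicate 2 stood apart from all other libraries, so the values without it are printed beside the counts of calls, and limma-voom with sample quality weights was added after seeing the data. No pair of replicates held identical values, and the lowest chi-square per degree of freedom between replicates was 8.8, above sampling noise.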

Results

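Gene expression was compared between 4 Iranian populations of the citrus red mite, a spider mite that feeds on citrus leaves. The populations differ in their response to fenpyroximate, a METI-I acaricide, which blocks complex I of the mitochondrial respiratory chain. Rasht was susceptible, Lahijan was moderately resistant, and Ramsar and Sari were highly resistant. Each population was represented by 4 libraries from pools of adult females. Expression was measured for 17682 assembled contigs, called transcripts here, of which 7516 carry the name of Rasht, 3565 that of Lahijan, 2998 that of Ramsar and 3603 that of Sari. The identifiers have no gene names, so functions were not analysed here. The libraries held 9154459 to 16595528 estimated counts, and 12174 transcripts were tested.

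With Rasht replicate 2 left out as a reference, each of the 16 libraries had its highest mean correlation, across transcripts, with its own population. For Rasht replicate 2 itself this was a near tie, at 0.821 with Rasht and 0.819 with Ramsar. Its highest correlation with a single library, 0.8391, was with Ramsar replicate 3. Replicates correlated at r = 0.972 to 0.976 in Lahijan, 0.967 to 0.98 in Ramsar and 0.973 to 0.984 in Sari, and at 0.811 to 0.975 in Rasht. These correlations are of log2 CPM across transcripts, which are not independent replicates. Rasht replicate 2 stood apart. It had no counts for 29.9% of transcripts, against 10.1% to 15.8% in the other 15 libraries, and its 100 most abundant transcripts took 45.6% of its counts, against 27.7% to 36.2%. Its correlation with any other library was 0.805 to 0.839, and that between any 2 of the others was at least 0.932. The median dispersion was 0.24 among the Rasht libraries and 0.019 among those of the other populations; without Rasht replicate 2 it was 0.043 and 0.02.

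**Figure D1:**
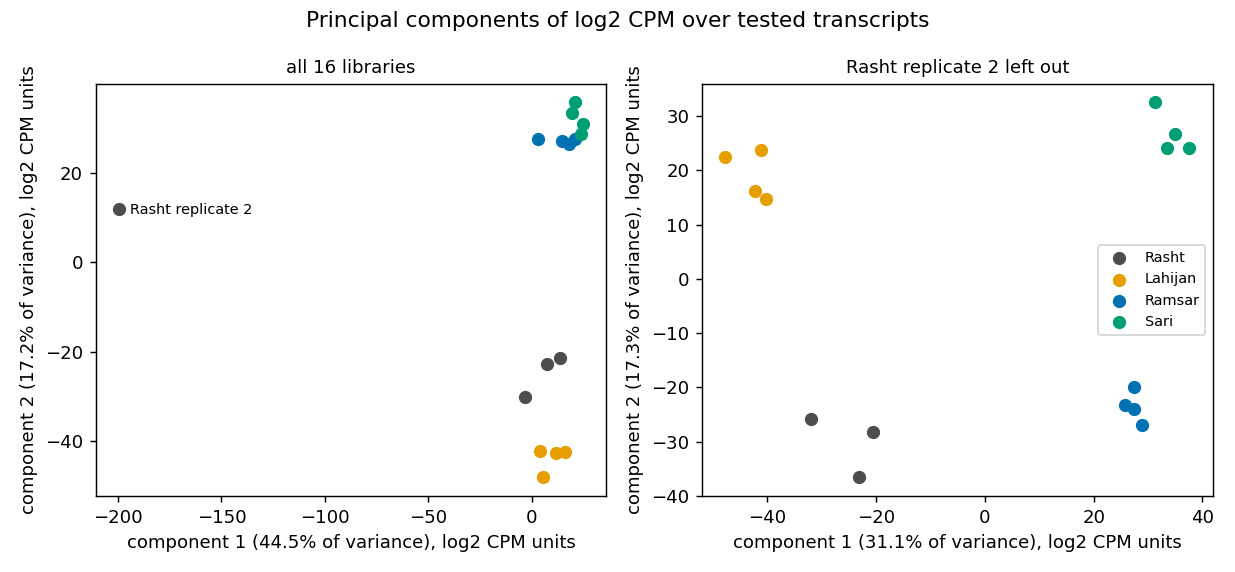
Principal components of log2 CPM over tested transcripts; each point is a library, coloured by population, and the axes give component scores in log2 CPM units. With all 16 libraries (left), component 1 holds 44.5% of the variance and parts Rasht replicate 2 from the rest; without it (right), component 1 holds 31.1% and parts Rasht and Lahijan from Ramsar and Sari, and component 2 holds 17.3%.

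The comparison of Lahijan with Rasht asks how a moderately resistant population differs from the susceptible one. Lahi_contig_3092 rose from 8.05 ± 2.71 TPM in Rasht to 1705 ± 337 TPM in Lahijan (SD, n = 4 each), a log2 fold change of 7.53 ± 0.76 (SE; edgeR adjusted p = 3.9e-05). Sari_contig_1087 rose from 3.36 ± 4.27 TPM to 285 ± 44.1 TPM, a log2 fold change of 6.4 ± 0.56 (edgeR adjusted p = 1.3e-05). Ramsar_contig_1016 was lower in Lahijan, at 0.616 ± 0.156 TPM against 8.85 ± 7.56 TPM in Rasht, with a log2 fold change of -4.52 ± 0.77 (edgeR adjusted p = 0.0024). Rasht_contig_2491 had 1.98 estimated counts over the 4 Lahijan libraries and 1197 over the 4 Rasht libraries, a scaled ratio of 568 with a 95% counting interval of 157 to 4692 (edgeR adjusted p = 0.019).

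In all, 404 transcripts were called between Lahijan and Rasht, 167 higher in Lahijan and 237 lower. Of these, 92.8% showed no overlap between the 4 libraries of each population, and over all tested transcripts 9.46% showed none, where chance gives 2.86%. With Rasht replicate 2 left out, 521 were called, 236 higher and 285 lower, and 340 of the 404 calls were kept. A fit of these 2 populations alone called 145, and its filter removed Rasht_contig_2491. Without Rasht replicate 3, Sari_contig_1087 had a log2 fold change of 7.69. The call of Rasht_contig_2491 rests on Rasht replicate 2, which held 17.1 TPM of it; without that library the scaled ratio was 85.6 (counting interval 23.3 to 714) and its edgeR adjusted p 0.12, without any 1 of the Lahijan libraries (replicates 1 to 4) it was 0.063, 0.062, 0.066 and 0.07, and over its alternatives it ranged from 3.4e-07 to 0.47. Ramsar_contig_1016 had a log2 fold change of -3.01 without that library (edgeR adjusted p = 0.00014). Its adjusted p ranged from 2e-09 to 0.062 over the alternatives, and its call was lost with limma-voom (0.062) and in the edgeR fit of these 2 populations alone (0.061).

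The comparison of Ramsar with Rasht sets a highly resistant population against the susceptible one. Sari_contig_5762 rose from 1.36 ± 0.612 TPM in Rasht to 9.44 ± 2.98 TPM in Ramsar (SD, n = 4 each), a log2 fold change of 2.37 ± 0.23 (SE; edgeR adjusted p = 8.7e-05). Lahi_contig_5684 was higher, at 9.05 ± 5.53 TPM in Ramsar against 1.2 ± 1.13 TPM in Rasht, with a log2 fold change of 2.57 ± 0.66 (edgeR adjusted p = 0.028). Lahi_contig_915 was lower, at 11.8 ± 4.84 TPM in Ramsar against 69.6 ± 34.5 TPM in Rasht, with a log2 fold change of -3.4 ± 0.52 (edgeR adjusted p = 0.0023). Rasht replicate 2 held 121 TPM of Lahi_contig_915, and without it the log2 fold change was -2.41 (edgeR adjusted p = 5.9e-05). In Lahijan and Sari the same transcript stood at 172 ± 32.9 and 157 ± 21.7 TPM. Ramsar_contig_286 was called lower in Ramsar (9.43 ± 2.48 TPM against 74.7 ± 126 TPM), but Rasht replicate 2 alone held 263 TPM. On the TPM scale the libraries overlapped, since Ramsar replicates 3 and 4 held 11.7 and 11.2 TPM and Rasht replicate 4 held 11.1 TPM. Without that library its log2 fold change was -0.59 and its edgeR adjusted p 0.19, within 0.014 to 0.27 over its alternatives.

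Between Ramsar and Rasht 492 transcripts were called, 279 higher in Ramsar and 213 lower. The 4 libraries of each population did not overlap for 85.2% of the calls and for 16.6% of tested transcripts, where chance gives 2.86%. This count depends on the Rasht libraries. It was 666 without Rasht replicate 2, with 521 higher and 145 lower, and 323 calls were kept. Further values were 790 without Rasht replicate 1, 1109 without Rasht replicate 3, and 310, 233, 293 and 268 without Ramsar replicates 1, 2, 3 and 4. A fit of these 2 populations alone called 10. DESeq2 called 873, and limma-voom put 77.1% of its calls on the higher side, against 56.7% in the edgeR model. Without Rasht replicates 1, 3 or 4 the share was 38.6%, 41.7% or 45.1%, so the side that held most calls depended on the library left out. Lahi_contig_5684 had a log2 fold change of 3.33 without Rasht replicate 1, and its call was lost without Rasht replicate 4 (edgeR adjusted p = 0.054) and without Ramsar replicates 1 or 2 (0.079 and 0.065), within a range of 0.00074 to 0.26 over its alternatives. The call of Lahi_contig_915 was lost in the fit of the 2 populations alone (edgeR adjusted p = 0.1, the highest over its alternatives, the lowest being 5.8e-10). Ramsar_contig_286 also lost its call without any 1 of Ramsar replicates 1 to 4 (edgeR adjusted p = 0.084, 0.093, 0.076 and 0.086).

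The comparison of Sari with Rasht, the other highly resistant population against the susceptible one, gave the most calls of the 6 comparisons in the edgeR model of all libraries (without Rasht replicate 2, both Sari and Ramsar against Lahijan gave more). Lahi_contig_246 rose from 179.7 ± 120 TPM in Rasht to 3805 ± 1251 TPM in Sari (SD, n = 4 each), a log2 fold change of 4.26 ± 0.5 (SE; edgeR adjusted p = 1e-04). Lahi_contig_3092, which also rose in Lahijan, stood at 184 ± 48.5 TPM in Sari, a log2 fold change of 4.18 ± 0.7 against Rasht (edgeR adjusted p = 0.0015). Lahi_contig_3068 fell from 38.2 ± 10.1 TPM to 0.121 ± 0.107 TPM, a log2 fold change of -8.76 ± 0.61 (edgeR adjusted p = 1.9e-06), while Lahijan and Ramsar held 35.6 ± 4.75 and 30.9 ± 6.07 TPM. Rasht_contig_5023 fell from 21.2 ± 1.87 TPM to 0.125 ± 0.202 TPM, a log2 fold change of -7.88 ± 0.67 (edgeR adjusted p = 1.4e-05). It stood at 25.1 ± 4.21 TPM in Ramsar and 7.1 ± 2.7 TPM in Lahijan. The log2 fold change of Lahi_contig_3068 was -8.13 without Rasht replicate 2 and -9.44 without Sari replicate 3, and that of Rasht_contig_5023 was -9.85 without Sari replicate 3.

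Between Sari and Rasht 1031 transcripts were called, 606 higher in Sari and 425 lower, and the libraries of the 2 populations did not overlap for 86.4% of them and for 24.6% of tested transcripts (2.86% by chance). Leaving out Rasht replicate 2 gave 1057 calls, 787 higher and 270 lower, and 663 were kept. Without Sari replicates 1, 2, 3 and 4 the count was 648, 644, 666 and 679, and a fit of these 2 populations alone called 246. The share of higher calls was 58.8%. It was 74.5% without Rasht replicate 2, 77.7% with limma-voom, and 46.5%, 47% and 46.8% without Rasht replicates 1, 3 and 4.

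**Figure D2:**
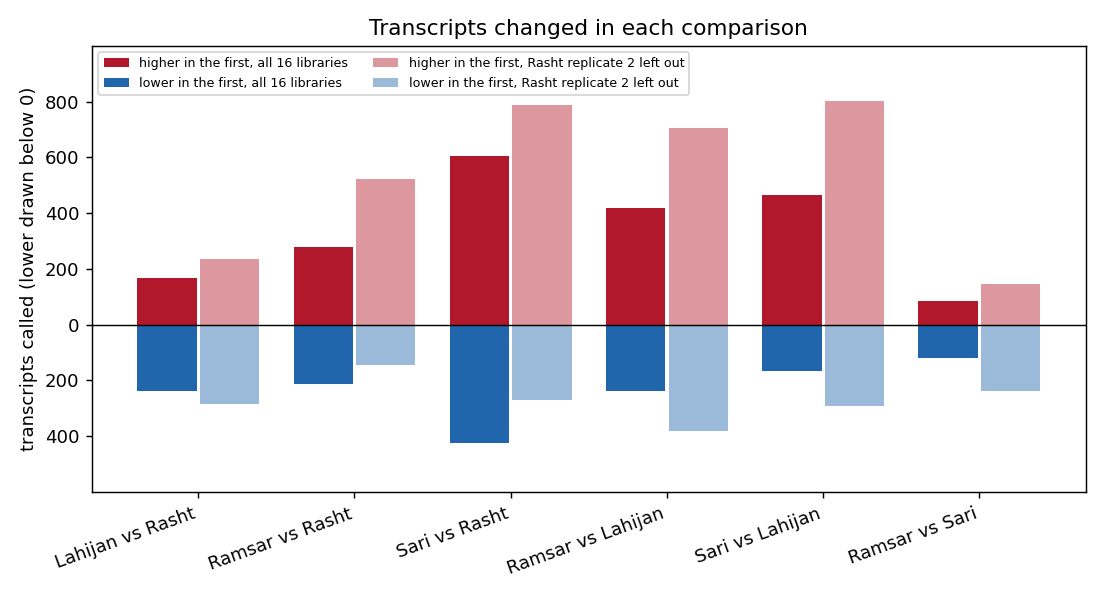
Transcripts called in each of the 6 comparisons; bars above 0 count transcripts higher in the population named first and bars below 0 those lower, with all 16 libraries (dark) and with Rasht replicate 2 left out (light). Sari against Rasht has 606 higher and 425 lower calls with all libraries and 787 and 270 without that library, and Ramsar against Sari has the fewest calls, 85 and 118.

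**Figure D3:**
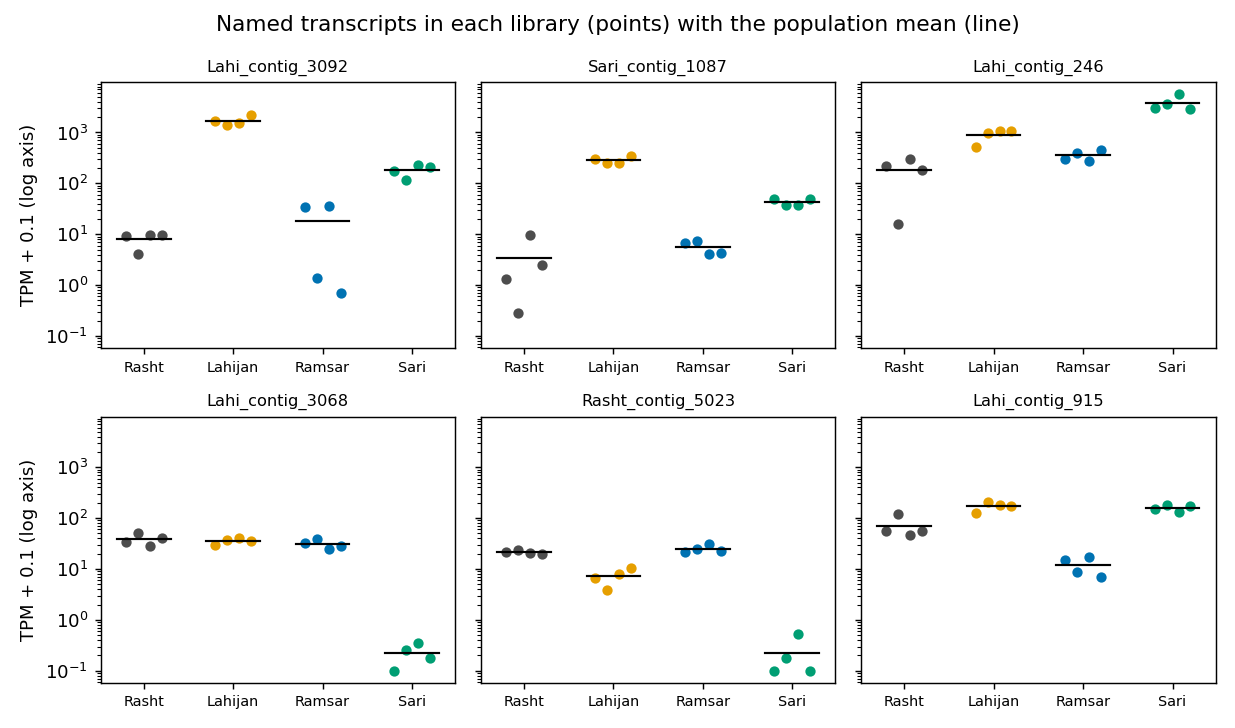
TPM + 0.1 on a log axis for 6 named transcripts; each point is a library, coloured by population, and the line is the population mean of 4 libraries. Lahi_contig_3068 lies between 24.1 and 50.8 TPM in all libraries of Rasht, Lahijan and Ramsar and at 0 to 0.25 TPM in Sari, and Lahi_contig_3092 lies between 1416 and 2189.7 TPM in Lahijan.

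The 3 comparisons use the same Rasht libraries. Changes were therefore set beside simulated groups with no change, in which the Rasht libraries kept their larger spread. For each transcript all Rasht libraries were given the same spread, whereas in the data Rasht replicate 2 alone stood apart. Groups simulated from all libraries hold for that setting only. Such groups alone gave a mean of 70.6 calls for Lahijan against Rasht, 76.2 for Ramsar against Rasht and 70.6 for Sari against Rasht, and 2.05, 1.95 and 2 without Rasht replicate 2. With all libraries, 219 transcripts were higher in both Ramsar and Sari than in Rasht and 94 were lower in both. Simulated unchanged groups gave 44 and 8.4 on average, independent lists of the same lengths would share 14 and 7.4, and splitting the Rasht libraries 2 and 2 between the comparisons left 165 to 218 and 27 to 58. Leaving out Rasht replicate 2 gave 397 and 44, against 1 and 0.25 in simulated groups and 33 and 3.2 for independent lists. For Lahijan and Sari, 83 were higher in both and 89 lower in both, against 42 and 8.4 simulated, 8.3 and 8.3 for independent lists, and 64 to 102 and 68 to 82 with split libraries; without Rasht replicate 2 the counts were 116 and 82, against 1.1 and 0.3 simulated and 15 and 6.3 for independent lists. For Lahijan and Ramsar, 24 were higher in both and 19 lower in both, against 44 and 8.2 simulated, 3.8 and 4.1 for independent lists, and 15 to 38 and 10 to 43 with split libraries; without Rasht replicate 2 they were 52 and 13, against 1.2 and 0.2 simulated and 10 and 3.4 for independent lists.

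Log2 fold changes against Rasht correlated across transcripts at r = 0.73 for Ramsar and Sari, 0.54 for Lahijan and Sari and 0.45 for Lahijan and Ramsar, while simulated unchanged groups gave 0.82 for each pair. With the Rasht libraries split, r was 0.23 to 0.33, 0.09 to 0.21 and -0.04 to 0.09. The covariance was 0.579, 0.445 and 0.321, against 0.283, 0.282 and 0.283 in simulated groups, a difference of 0.296 for Ramsar and Sari, 0.163 for Lahijan and Sari and 0.038 for Lahijan and Ramsar. With Rasht replicate 2 left out, r was 0.68, 0.45 and 0.32, against 0.62, 0.63 and 0.63 simulated, so that for Ramsar and Sari it lay above the simulated value and with all libraries below it; the differences in covariance were 0.385, 0.205 and 0.082.

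Called the same way in all 3 resistant populations were 36 transcripts, 22 higher and 14 lower than in Rasht. Simulated unchanged groups gave 38 higher and 6.4 lower, so with all libraries the higher count did not exceed the simulated one. These groups gave all Rasht libraries the same spread for each transcript, whereas in the data Rasht replicate 2 alone stood apart. What the shared Rasht libraries give without any effect is therefore known only under that setting. Without Rasht replicate 2, 47 were higher and 7 lower, against 1 and 0.2 in simulated groups and 0.64 and 0.074 for independent lists. The larger side also depended on the Rasht libraries, with 19 higher and 45 lower without Rasht replicate 1, 36 and 66 without Rasht replicate 3, and 21 and 31 without Rasht replicate 4. The count of 36 was 64 without Rasht replicate 1, 102 without Rasht replicate 3, 22, 21 and 21 without Lahijan replicates 1, 2 and 4, 22, 16, 19 and 16 without Ramsar replicates 1 to 4, and 21, 22 and 23 without Sari replicates 2, 3 and 4. Transcripts called in both Ramsar and Sari but not in Lahijan numbered 197 higher and 80 lower, and 347 and 36 without Rasht replicate 2; a call missed in Lahijan is not a test of a difference. In 11 transcripts, and in 22 without Rasht replicate 2, 2 resistant populations were called in opposite directions against Rasht.

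The direct comparisons of the resistant populations ask whether the moderately and the highly resistant ones differ. Ramsar_contig_7025 had 0 estimated counts in all 4 Lahijan libraries and stood at 22.2 ± 4.09 TPM in Ramsar and 22.5 ± 1.77 TPM in Sari. Against Lahijan it was at least 537-fold higher in Ramsar (edgeR adjusted p = 0.0029) and at least 567-fold higher in Sari (edgeR adjusted p = 0.0031). In Rasht it stood at 1.95 ± 2.51 TPM. Neither Ramsar nor Sari was called against Rasht (edgeR adjusted p = 0.11 and 0.088), while Lahijan was called lower than Rasht (edgeR adjusted p = 0.029). Rasht_contig_2491 stood at 10.6 ± 8.49 TPM in Ramsar and 18.4 ± 5.12 TPM in Sari. In Rasht it stood at 5.24 ± 8.08 TPM, and neither Ramsar nor Sari was called against Rasht (edgeR adjusted p = 0.94 and 0.72). Its 1.98 counts in Lahijan put the ratio at 614 for Ramsar (counting interval 169.7 to 5074; edgeR adjusted p = 0.013) and 1111 for Sari (307 to 9177; edgeR adjusted p = 0.0079). Both calls of this transcript were lost with limma-voom (adjusted p = 0.24 and 0.14, the highest over the alternatives, the lowest being 5.6e-07 and 3.6e-08). Lahi_contig_3092 and Sari_contig_1087 were lower in Ramsar than in Lahijan, at 17.9 ± 19.7 and 5.56 ± 1.71 TPM (edgeR log2 fold changes of -6.79 ± 0.72 and -5.96 ± 0.54, adjusted p = 4.1e-05 and 1e-05). Lahi_contig_3068 and Rasht_contig_3383 were lower in Sari than in Lahijan by edgeR log2 fold changes of -8.23 ± 0.6 and -6.64 ± 0.57 (adjusted p = 3e-06 and 1.2e-05). Rasht_contig_3383 stood at 0.127 ± 0.118 TPM in Sari, 12.5 ± 3.43 in Lahijan, 12.3 ± 3.22 in Rasht and 10.1 ± 3.22 in Ramsar. Leaving out Ramsar replicate 3 gave Lahi_contig_3092 a log2 fold change of -7.44 between Ramsar and Lahijan, limma-voom gave -8.3, and limma-voom with sample quality weights gave -9.29. Leaving out Sari replicate 3 gave Lahi_contig_3068 and Rasht_contig_3383 -8.92 and -7.33.

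Between Ramsar and Lahijan 655 transcripts were called, 417 higher in Ramsar and 238 lower, and between Sari and Lahijan 632, of which 466 were higher in Sari and 166 lower. The libraries did not overlap for 97.6% and 98.6% of these calls, and for 27.6% and 36.3% of tested transcripts, where chance gives 2.86%. Rasht replicate 2 is in neither group of these contrasts and entered through the filter, the scaling and the shared estimate of the spread. Without it 1084 and 1093 were called, and 655 and 631 of the calls were kept.

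Ramsar and Sari, both highly resistant, differed in 203 transcripts, 85 higher in Ramsar and 118 lower. This was the smallest count of the 6 comparisons in the edgeR model of all libraries. Lahi_contig_3068 and Rasht_contig_5023 were higher in Ramsar by edgeR log2 fold changes of 7.72 ± 0.6 and 7.47 ± 0.67 (adjusted p = 6.1e-06 and 2e-05). Rasht_contig_96 stood at 19.4 ± 10.7 TPM in Ramsar and 412 ± 119.8 TPM in Sari, a log2 fold change of -4.47 ± 0.36 (edgeR adjusted p = 6.1e-06). It stood at 77 ± 33.7 TPM in Rasht and 276 ± 49.6 TPM in Lahijan. Against Rasht it was called lower in Ramsar (log2 fold change -2.45) and higher in Lahijan (1.7) and Sari (2.02). Lahi_contig_241 stood at 3.24 ± 0.804 TPM in Ramsar and 127 ± 122 TPM in Sari, a log2 fold change of -5.37 ± 0.92 (edgeR adjusted p = 0.0044). Rasht held 10.3 ± 10 TPM and Lahijan 98 ± 61.6 TPM of it, and Sari was not called against Lahijan (edgeR adjusted p = 0.93). The libraries did not overlap for any of the 203 calls, and for 15.4% of tested transcripts. Leaving out Rasht replicate 2 gave 382 calls, and 201 were kept. Without Sari replicate 3 the log2 fold changes of Lahi_contig_3068, Rasht_contig_5023 and Lahi_contig_241 were 8.4, 9.44 and -4.4. The call of Lahi_contig_241 was lost with limma-voom (adjusted p = 0.054, the highest over its alternatives, the lowest being 8.9e-11).

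In all, 111 transcripts were called the same way in both Ramsar and Sari against both Rasht and Lahijan, a criterion that sets no order between Rasht and Lahijan. Of these, 103 were higher in the highly resistant populations and 8 lower. The count was 244 without Rasht replicate 2, 225 higher and 19 lower, and without Ramsar replicate 2 there were 73. The 4 comparisons behind this count share their libraries. Simulated unchanged groups gave a mean of 0 in each direction, with and without Rasht replicate 2. That value was set by the simulation, which gave a mean of 0 calls for Ramsar against Lahijan and 0.05 for Sari against Lahijan. Without Rasht replicate 2 these means were 0.05 and 0.1. It therefore does not show what shared libraries give where the populations differ. Higher than both Rasht and Lahijan were 131 transcripts in Ramsar and 245 in Sari, and lower 56 and 67. Independent lists of these lengths would share 2.6 and 0.31. Without Rasht replicate 2 the lists held 304 and 443 higher and 93 and 111 lower, and independent lists of those lengths would share 11 and 0.84. With the Rasht and the Lahijan libraries each split 2 and 2, so that Ramsar and Sari were set against different libraries, 36 splits left 28 to 62 higher and 2 to 4 lower, from fewer libraries per group. Sari_contig_5762 was among those higher, at 1.36 ± 0.612 TPM in Rasht, 2.34 ± 0.257 in Lahijan, 9.44 ± 2.98 in Ramsar and 10.2 ± 1.42 in Sari, and its difference between Lahijan and Rasht was not called (log2 fold change 0.69, edgeR adjusted p = 0.13).

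The share of transcripts called differed with the population named in the identifier. Between Sari and Rasht, 12.5% of the 1972 tested transcripts named for Sari were higher in Sari and 1.62% lower, while of the 6399 named for Rasht 1.75% were higher and 3.86% lower. Without Rasht replicate 2 these shares were 16.5% and 0.863% of the transcripts named for Sari and 1.97% and 2.24% of those named for Rasht. Between Ramsar and Rasht, 1.17% of those named for Rasht were higher in Ramsar and 1.56% lower, and 1.58% and 0.86% without Rasht replicate 2, so there the larger side turned away from the name. Between Lahijan and Rasht, 4.71% of the 2229 named for Lahijan were higher in Lahijan and 0.269% lower (6.33% and 0.135% without Rasht replicate 2). Over the 6 comparisons, 1865 calls fell on transcripts named for one of the populations compared, and 81.1% of them were higher in the population they are named for (81% of 2450 without Rasht replicate 2). Transcripts with fractional counts, taken to share reads with another contig, were called more often than those with whole counts. Between Sari and Rasht 7.17% of the former were higher and 4.33% lower, against 2.12% and 2.4% of the latter. The shares were 9.05% and 3.3% against 2.74% and 0.681% without Rasht replicate 2.

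**Figure D4:**
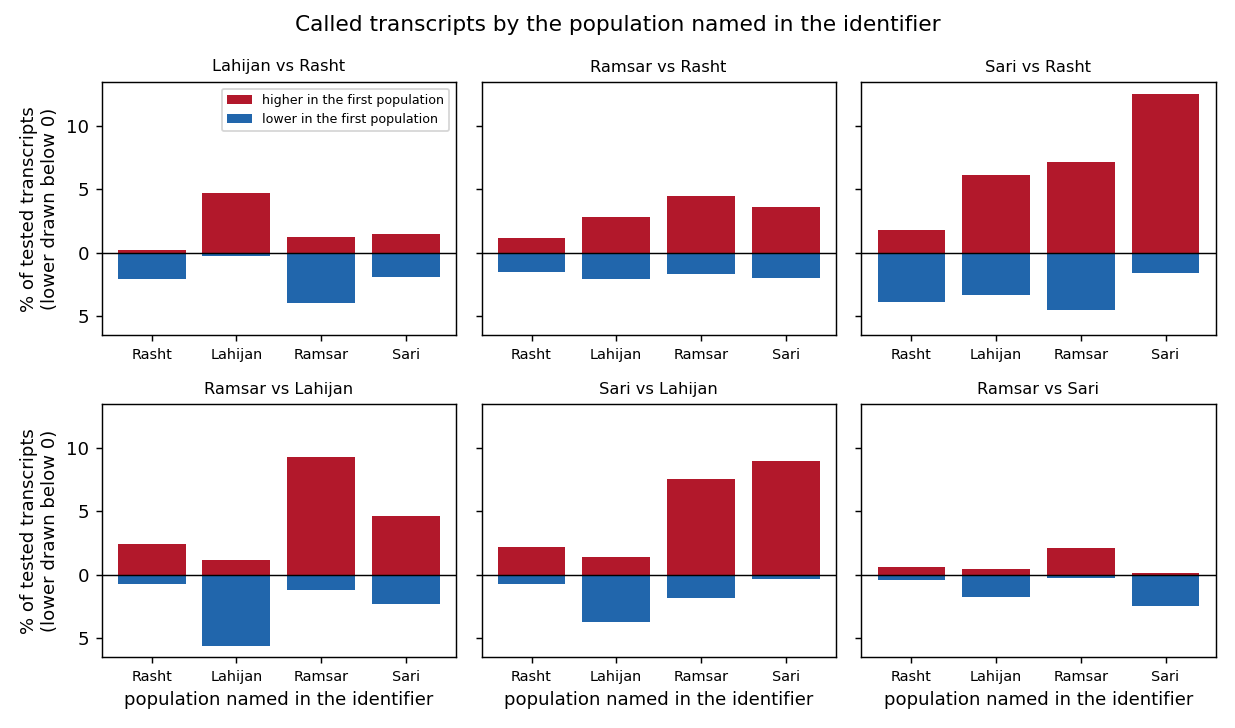
Percent of tested transcripts called higher (above 0) or lower (drawn below 0) in the population named first, for each comparison (panels) and by the population named in the identifier (bars). Between Ramsar and Lahijan 9.28% of transcripts named for Ramsar were higher in Ramsar, and 5.61% of those named for Lahijan were lower, with all 16 libraries; without Rasht replicate 2 these were 15.3% and 8.31%.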

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

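The tests of a label exchange and of transcript length for Rasht replicate 2, that of the population name for the excess of higher calls, its counts by abundance, and the intervals from transcripts drawn again, were chosen only after the result was seen. A library was listed where its gap to the nearest of the other 3 libraries was unusually large for 4 values, which chance gives in about 5% of groups; 9 of 80 groups were listed, 7 of them for Rasht replicate 2.

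Rasht replicate 2 lay far from the other Rasht libraries in the share of transcripts with no counts (29.9%), the share of counts in its 100 most abundant transcripts (45.6%) and its TMM factor (0.529). It also did so in the TPM of Lahi_contig_3092 (3.99), Ramsar_contig_1016 (20.1), Ramsar_contig_286 (263) and Lahi_contig_915 (121). An exchange of labels with another library is argued against by the other 15 libraries. With Rasht replicate 2 left out as a reference, 0 of them correlated better with another population than with their own. The deviations of Rasht replicate 2 from the other Rasht libraries ran with transcript length. Their median went from 0.58 on the log2 scale among the shortest 2353 transcripts to -0.76 among the longest 2354. Their SD was 1.9 over all tested transcripts, and 1.86 after that trend was removed, over the 11769 with a length estimate. The latter was 3 times the largest SD of another Rasht library after the same step. Its 95% interval, 2.86 to 3.13, came from transcripts drawn again, which are not independent, and leaves out differences between libraries. Length therefore accounts for little of the SD of these deviations. Few starting molecules cannot be told apart from other sources. Among the 243 most abundant transcripts the ratio was 2.28, with an interval, made in the same way, of 1.81 to 2.9 around the bound of 2. In addition, 164 transcripts with over 100 counts on average in the other Rasht libraries had none here. A biological difference of this pool of mites stays open and was not tested.

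Called transcripts tended to be higher in the population their identifier names. This held for 81.1% of 1865 calls on transcripts named for a population compared, and 81% of 2450 without Rasht replicate 2. An odds ratio compared the direction of these calls between transcripts named for either of the populations compared. It can be large even where transcripts with a given name mostly go against that name. It was 19.2 (95% interval 14.9 to 24.8), and 25.9 (20 to 33.5) without Rasht replicate 2. These intervals pool calls over 6 comparisons that share libraries and transcripts, so the calls are not independent; drawing whole transcripts again gave 14.2 to 26.2 and 19.2 to 37, which still leaves out the shared libraries. Reads split between near-identical contigs are argued against as the whole cause of how the direction depends on the name. Among transcripts with whole counts in every library the odds ratio was 9.95 (5.11 to 19.4), and 13.2 (5.86 to 29.7) without Rasht replicate 2. Drawing these transcripts again gave intervals of 5 to 23.4 and 5.8 to 66.9. The share of calls in the direction of the name was lower there, at 68.6% of 388 and 60.2% of 384 without Rasht replicate 2, against 81.1% and 81% over all tested transcripts, so a part from shared reads is not excluded. Without that library, transcripts with whole counts named for Rasht went mostly against their name in Ramsar and Sari. There 50 were higher and 10 lower in Ramsar, and 61 higher and 23 lower in Sari, than in Rasht. In Lahijan they mostly followed it, with 11 higher and 22 lower than in Rasht. A candidate explanation is that a contig was assembled mainly where its transcript was abundant, so that the name follows expression. Sequence variants that keep reads of one population from matching the contig of another are also open, and neither was tested because no sequences were used.

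Higher calls outnumbered lower calls in Ramsar and Sari against Lahijan, with 68.6% of 1287 calls higher (95% interval 66% to 71.1%; calls are not independent). Names are argued against as the whole cause, since 75.4% (70.8% to 79.6%) were higher among transcripts named for Rasht, a population outside these comparisons. The choice among the scaling factors is argued against too, since the lowest share under DESeq2 size factors and upper-quartile factors was 68.1%. These moved the median log2 fold change of the 2 comparisons only by -0.014 to 0.02. An error that all the scalings share could therefore not be seen. The excess depended on abundance. Among the 2434 least abundant tested transcripts 124 were higher and 54 lower in Ramsar, and 142 and 41 in Sari, but among the 2435 most abundant 16 were higher and 39 lower in Ramsar, and 18 and 21 in Sari. Without Rasht replicate 2 these were 280 and 106, 343 and 95, 18 and 51, and 23 and 28. What ties the excess to abundance was not tested, so its cause stays open; a biological difference between the populations is among the open explanations, and the resistance level cannot be separated from the population in this design.

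A further pair of libraries lay far from their replicates: Sari replicate 4 had 10.81 M estimated counts (M, counts times 1e+06), and Ramsar replicate 4 held 2.16 TPM of Ramsar_contig_1016.

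For the named transcripts of the comparisons against Rasht, the difference between the changes of 2 resistant populations was tested with edgeR, and 17 of 23 had an adjusted p under 0.05. These transcripts were chosen for large changes, so this share says nothing of transcripts in general: of all 12174 tested, 1046 differed at that threshold between Ramsar and Lahijan, 1137 between Sari and Lahijan and 276 between Ramsar and Sari. The log2 change against Rasht of Lahi_contig_3092 in Lahijan exceeded that in Ramsar by 6.79 and that in Sari by 3.35, and its change in Sari exceeded that in Ramsar by 3.44. For Sari_contig_1087 the change in Lahijan exceeded that in Ramsar by 5.96 and that in Sari by 2.96. For Rasht_contig_2491 the fitted change in Lahijan minus that in Ramsar was -9.01 and minus that in Sari -9.82, values that depend on the prior count. For Ramsar_contig_1016 the change in Lahijan minus that in Ramsar was -2.93. For Sari_contig_5762 the change in Ramsar exceeded that in Lahijan by 1.68. For Lahi_contig_915 the change in Ramsar minus that in Lahijan was -4.16 and minus that in Sari -3.76. For Lahi_contig_246 the change in Sari exceeded that in Lahijan by 1.93 and that in Ramsar by 3.49. For Lahi_contig_3068 the change in Sari minus that in Lahijan was -8.23 and minus that in Ramsar -7.72, and for Rasht_contig_5023 these were -5.92 and -7.47.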

How the results depend on the processing

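All alternatives except the sample quality weights were chosen before the data were examined. Of 173 recomputed counts and correlations, 129 stayed within 1.5 times the reported count or 0.1 of the correlation, among them all of those under DESeq2 size factors, upper-quartile factors, no filter, the filter of CPM 1 in 4 libraries, and limma-voom. For the named transcripts, 377 of 404 alternatives kept direction and call, 27 lost the call, 13 of these with a library left out, and 0 reversed. Left out of the 404 were 3 for which DESeq2 gave no adjusted p. Rasht_contig_2491 was also left out in the fit of Lahijan and Rasht alone, where the filter removed it. DESeq2 called 873 transcripts between Ramsar and Rasht, 314 between Ramsar and Sari, and 79 the same way in all 3 resistant populations. Fits of the 2 populations alone called 145 between Lahijan and Rasht, 10 between Ramsar and Rasht, 246 between Sari and Rasht, 1015 between Sari and Lahijan and 371 between Ramsar and Sari; such a fit gives each pair its own spread. The adjusted p alone, which drops the minimum change, called 1111 between Ramsar and Rasht, 2232 between Sari and Rasht, 1046 between Ramsar and Lahijan, 1137 between Sari and Lahijan, 72 in all 3 and 257 in both highly resistant populations against both others. With sample quality weights, limma-voom called 1273 between Ramsar and Lahijan, 1288 between Sari and Lahijan, 588 between Ramsar and Sari and 259 in both highly resistant populations against both others; Rasht replicate 2 had a weight of 0.0232. Leaving out 1 library of the populations compared gave 299 to 521 for Lahijan against Rasht, 233 to 1109 for Ramsar against Rasht, 644 to 1516 for Sari against Rasht, 486 to 559 for Ramsar against Lahijan, 473 to 505 for Sari against Lahijan, 147 to 178 for Ramsar against Sari, 16 to 102 for all 3, and 73 to 244 for both highly resistant populations against both others. Except as stated, the cause of these shifts was not tested.

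No clear pairing by replicate number was seen: the deviations of same-numbered libraries from their population means correlated at -0.251 to 0.177, with 3 of 24 pairs over 0.1. Pairs with different numbers were not set beside them, and Rasht replicate 2 shifts the Rasht mean, so pairing is not excluded. With the replicate number as a block, 324 transcripts were called between Ramsar and Rasht and 14 the same way in all 3, and the other counts stayed within 1.5 times. The gene list tests and their alternatives were not run, because no identifier matched a list. The pseudocount alternatives were for a table without counts and were not run. Depth limits transcripts with few counts: no fold is given against a population with 0 counts beyond the bound that 3 counts allow.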

Other observations

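The presence of transcripts in 1 population only was looked at after the data were seen. Present at 1 TPM or more in every Sari library, with at most 3 counts in any other library, were 22 transcripts, 16 of them named for Sari. The count for Ramsar was 10, of which 6 were named for Ramsar. Lahijan, Rasht and the transcripts missing from 1 population each had counts of at most 5. Without Rasht replicate 2 the counts were 23 for Sari, 13 for Ramsar and 9 for Rasht, and 12 transcripts were missing from Lahijan only.

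Higher calls in Sari were mostly of transcripts with low abundance. Between Sari and Lahijan, 5.83% of the 2434 least abundant tested transcripts were higher in Sari and 1.68% lower, and of the 2435 most abundant 0.739% were higher and 0.862% lower. Between Sari and Rasht the least abundant class had 9.41% higher and 3.7% lower, and the most abundant class 0.698% higher and 4.93% lower. In the latter the lower calls depended on Rasht replicate 2: without it 0.821% of the most abundant class were higher and 1.07% lower.

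Other splits of the 8 libraries of each comparison were fitted with only those libraries, 35 splits each with the real one included. For each comparison 1 of the 35 splits, the real one, reached the real count. The real count and the highest of the other splits were 145 and 0 for Lahijan against Rasht, 10 and 1 for Ramsar against Rasht, 246 and 0 for Sari against Rasht, 970 and 0 for Ramsar against Lahijan, 1015 and 3 for Sari against Lahijan, and 371 and 1 for Ramsar against Sari. The comparisons share libraries, and this share was not corrected for testing several of them. For each comparison taken singly, these splits argue against labels given at random, at 1 of 35, the least share they can give. A difference in spread is not excluded by them: with all libraries, simulated unchanged groups that keep the larger spread of Rasht gave a mean of 70.6 to 76.2 calls against Rasht. Splits that mix populations add the differences between them to the spread, which lowers their own counts, so the gap to the real count is no measure of its size.

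Among 60 groupings of the 16 libraries into 4 groups, 1, the real one, reached the 36 transcripts changed the same way in all 3 resistant populations, and 1 reached the 111 in both highly resistant populations against both others. The highest of the other groupings was 0 for each. Mixed groupings lower their own counts here too and leave out the spread of the shared Rasht libraries. They argue against labels given at random, at 1 of 60, but do not show that the 36 exceed what that spread gives. Simulated unchanged groups, which give that spread to all Rasht libraries alike, gave 38 higher and 6.4 lower, against 22 and 14 observed. For the 111 such groups gave a mean of 0 in each direction. That value followed from their near lack of calls against Lahijan, so it does not test the effect of shared libraries. None of these splits separates resistance from any other difference between the populations.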
